A study of Homo sapiens with 41 samples.

How the data were processed

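Total RNA from 41 pinch biopsies of intestinal mucosa, given by 26 people with inflammatory bowel disease, was measured on 1-colour Agilent expression arrays, 1 array per biopsy. Per the labels the biopsies were snap-frozen and the RNA was labelled with Cy3. The labels give the disease (ulcerative colitis, UC, or Crohn's disease, CD), the state of the mucosa (normal, inactive or active) and the gut segment, and these were taken as they stand. The number that titles share was read as the donor. The series text also mentions sorted T cells and microbial data, which are not part of the deposited files and were not examined.

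Per the file headers, the scanner files hold spot signals as intensity, background-subtracted and detrended by Agilent Feature Extraction 10.7.3.1, and not normalized between arrays. They also hold the median intensity of each spot and of its local background, and flags for spots well above background, not uniform or saturated. The deposited value table holds log2 values which the authors had quantile normalized, judging by the values: the column medians lay between 9.66 and 9.66, and each column correlated with the log2 median signal of its own array with r between 0.983 and 0.999 across spots, which are not independent replicates. No text states the software behind this table. The arrays came from 6 slides and 1 scan day, under the protocol names GE1_107_Sep09 and GE1_107_Sep09_2. The name GE1_107_Sep09_2 was that of slide 3 alone, with 6 of the 7 UC active arrays and 1 CD normal array. The protocol thus goes with the slide and largely with the UC active group. Among the 58717 non-control spots, none was saturated and no array was a copy of another. Among the spots of the probes used, 2664 values were marked as not uniform. They were masked, except where all spots of a probe on an array were marked, in which case the value was kept. The mask was not applied under quantile normalization, normexp or the deposited value table.

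Each array carries 62976 spots, of which 4259 are controls and were left out. Spots of 1 probe were averaged, giving 42405 distinct probes. Of these, 26364 carried a RefSeq accession that the supplied table pairs with 1 gene symbol, and 16041 did not and were left out. Sex-linked marker probes (104) were removed before any step. A probe was kept if it was well above background on at least 7 of the 41 arrays. Where several probes of 1 gene were kept, the brightest stood for the gene. This left 19570 genes tested. Values are log2 of the processed signal minus the log2 75th percentile of the same array, so 0 stands for the array's 75th percentile. The files give no genome build or coordinates that were used, and genes are identified by symbol. SAA1 was read by a single probe, and the paralog SAA2 has a closely similar transcript, so part of that signal can come from SAA2.

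Counts of molecules do not exist for arrays, so the number of arrays limits the precision. Between 84.9% and 98.6% of the non-control spots of an array were well above background (median 95.3%). The log2 75th percentile ran from 9.43 to 12.24 over the arrays.

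All 41 biopsies were fitted together with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a term for each of the 6 groups, a fixed term for the gut segment and the donor as a random replicate block. Of the 26 donors, 15 gave 2 biopsies, and the fitted correlation within donors was 0.0338. For UC active against UC normal, the no-block count was 1057 genes and with the donor as a fixed replicate block it was 174, against 1009 with the random block. For CD active against CD normal, these counts were 2580, 2 and 2550. Moderated tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. In these pages "rose" and "fell" are used of called genes and lists. Fold changes are given on the log2 scale with their standard error (SE), and group levels with their standard deviation (SD). Where no array of the lower group was above background, the fold is given as a lower bound, computed with each array's lowest value well above background as the floor.

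Named genes were chosen by a rule written before the data were examined. It takes SAA1 in every comparison. It then takes the 12 largest rises and 12 largest falls among called genes in each of the 2 comparisons of active with normal mucosa, and 6 of each elsewhere, provided that the gene was well above background on 50% or more of the arrays of the higher group. Names that are only a clone, an accession or a reading frame, and segments of immunoglobulin and T cell receptor genes, were passed over. From each gene list it takes up to 4 members with the smallest adjusted p. A part of the genes the rule allows is named here. The 32 gene lists were also fixed before the data were examined, from textbook knowledge, and were not chosen on these samples. They cover inflammatory pathways, markers of immune, stromal and epithelial cell types, gut regions, and responses to handling. The list members FCGR3B, FCGR1A, HBA1 and SULT1A1 were not measured on any kept probe. Lists were tested against all other genes with camera at a preset correlation between genes of 0.01, with adjustment over the 32 lists of a comparison, and beside that with the correlation estimated per list. The self-contained test fry was also run, which asks whether a list's members move on balance one way.

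The relation of SAA1 to 12 genes of TH17, TH22, epithelial and T cell biology was computed over 26 donors, each with 1 value, the mean of its residuals after the group and the segment were removed. Pearson's r and Spearman's rho were each tested with 100000 permutations, two-sided, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and adjusted over the 12 genes. Figures were drawn with matplotlib 3.10.9.

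The alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the deposited value table, no filter on dim probes, a filter asking for signal well above background on all arrays, no replicate block, the donor as a fixed block, no segment term, colonic biopsies only, the slide as a random or a fixed block, an added log2 fold change threshold of 1, the mean over probes, and each biopsy left out in turn. The planned mean spot signal was absent from the scanner files, so the median spot signal took its place under normexp. Added after the data were seen were the brighter genes only (above the median over the genes tested), the same with the slide as a random block, the fit without 3 UC normal arrays whose processed signal correlated least with their value table column, and the difference of means within a slide that holds both groups. Each count of genes was set against 100 splits of the same biopsies.

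The fit was tested on simulated data with the same design and 200 changed genes among 19570. In the UC comparison of active with normal mucosa it recovered 26.9%, 50.7% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 3 unchanged genes called. In the CD comparison it recovered 26.9%, 55.2% and 84.8%, with 4 unchanged genes called. In each of the 2 comparisons both raised lists were called and none of the others. The simulated genes varied independently of each other and carried no slide effect. These values therefore do not give the error rates of the real arrays, where groups lay largely on separate slides.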

Results

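Gene expression was measured in mucosa from 22 UC biopsies of 14 donors and 19 CD biopsies of 12 donors. The UC biopsies comprised 8 from normal, 7 from inactive and 7 from active mucosa. The CD biopsies comprised 10 from normal, 2 from inactive and 7 from active mucosa. By segment, 20 biopsies came from the distal colon, 17 from the proximal colon and 4 from the ileum, and the ileal ones were all from CD. The series title names SAA1, an acute-phase protein made by inflamed epithelium, in connection with TH17 and TH22 cells, so SAA1 is given in every comparison. The groups lay largely on separate array slides. All 8 UC normal arrays were on slide 1, all 7 UC inactive arrays on slide 2 together with 1 UC active array, and 6 UC active arrays on slide 3 together with 1 CD normal array. Slide 4 held 8 CD normal arrays, slide 5 held 5 CD active, 2 CD inactive and 1 CD normal array, and slide 6 held 2 CD active arrays. By group median, the share of spots well above background was lowest among UC inactive arrays (92.1%, range 88.4% to 92.2%), against 95.5% among CD active arrays (89.7% to 98.1%) and 94.6% among UC normal arrays, which held the lowest single array (84.9% to 98.6%).

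In CD, active mucosa was compared with mucosa labelled normal to find what accompanies inflammation in this disease. Genes of epithelial defence and innate inflammation rose, and genes of the mature absorptive colonic lining fell. SAA1 rose 19.8-fold (log2 4.30, SE 1.09, adjusted p = 0.00963) and lay above the CD normal mean in 7 of 7 active biopsies, from a level of −4.43 ± 1.07 (SD, n = 10) to −0.62 ± 2.11 (SD, n = 7). REG1A, a secreted lectin of regenerating epithelium, rose 47.7-fold (log2 5.58, SE 1.77). DUOX2 and DUOXA2, which together make hydrogen peroxide at the epithelial surface, rose by log2 3.49 (SE 0.96) and 4.12 (SE 1.29). In all, 999 genes rose and 1551 fell of 19570 tested. The count of 2550 fell to 897 without CD active replicate 7 and to 1149 without CD active replicate 2. A fit with the slide as a random block in place of the donor gave 7 rises and 10 falls, and SAA1 kept its size without the call (log2 4.56, adjusted p = 0.0956, against adjusted p from 0.00312 to 1 over the settings other than single biopsies left out). With the donor as a fixed replicate block, only 1 donor with both states in 1 segment, the ileum, informs the estimate. Under that block 2 rose and none fell, and SAA1 was at 0.27.

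**Figure D1:**
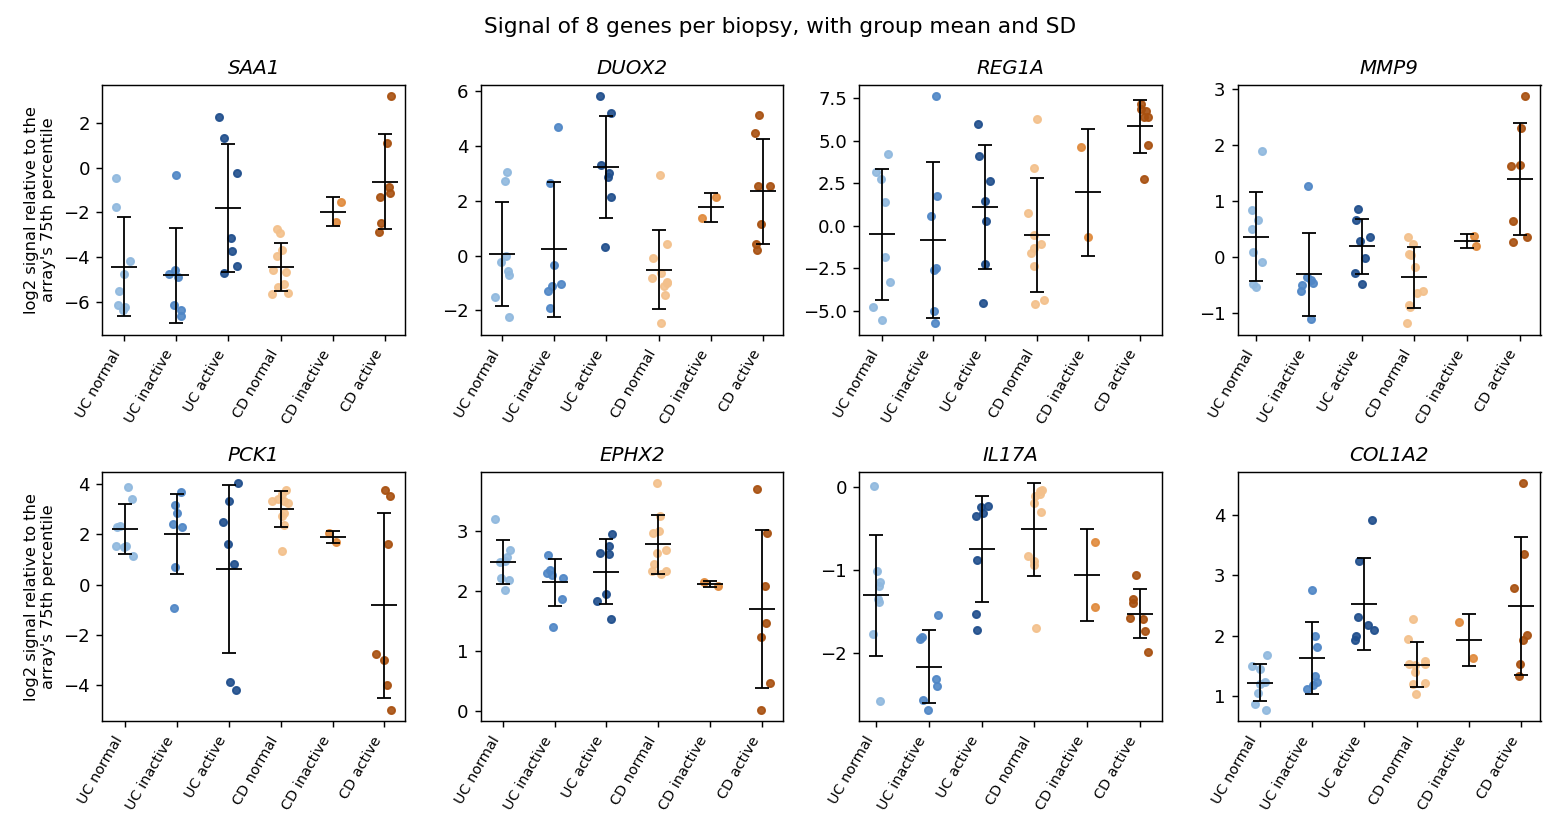
Log2 signal relative to each array's 75th percentile (y axis) of 8 genes in each biopsy (points) by group (x axis), with the group mean and SD (black). SAA1 lies at −0.62 ± 2.11 in the 7 CD active and at −4.43 ± 1.07 in the 10 CD normal biopsies, and IL17A lies lower in CD active (−1.53 ± 0.30) than in CD normal (−0.51 ± 0.56) biopsies.

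Of 19 acute-phase and antimicrobial genes, 11 rose (15 adjusted over the list alone) and the other 8 were higher without passing the test, with a median log2 fold change of 2.59 (camera adjusted p = 5.31e-09, and adjusted p = 0.21 with an estimated correlation). Among them S100A8 and S100A9, the subunits of calprotectin, rose by log2 3.68 (SE 0.95) and 2.73 (SE 0.73), and IDO1, which degrades tryptophan, by 2.30 (SE 0.60). Of 15 inflammatory cytokines and chemokines, 6 rose (8 adjusted over the list alone) and none fell (median 1.19, adjusted p = 2.11e-06, and adjusted p = 0.21 with an estimated correlation). CXCL8, CXCL1 and CXCL3, which attract neutrophils, rose by log2 4.26 (SE 1.00), 3.15 (SE 0.91) and 3.15 (SE 0.90), and IL1B by 2.15 (SE 0.64). Neutrophil markers moved with them, as 4 of 9 rose (4 adjusted over the list alone, median 0.98, adjusted p = 0.000383, and adjusted p = 0.269 with an estimated correlation), among them PROK2 at log2 3.67 (SE 1.05), AQP9 at 1.72 (SE 0.48), FPR1 at 2.05 (SE 0.62) and MNDA at 1.16 (SE 0.33).

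Matrix-degrading enzymes and their partners rose, with 7 of 10 called (8 adjusted over the list alone, median 2.09, adjusted p = 4.94e-07, and adjusted p = 0.21 with an estimated correlation). CHI3L1, a chitinase-like glycoprotein, rose by log2 4.89 (SE 1.00), MMP3 by 4.15 (SE 0.86), MMP7 by 3.29 (SE 0.89) and MMP9 by 1.96 (SE 0.37). Fibroblast and collagen genes rose in 6 of 11 cases (8 adjusted over the list alone, median 1.10, adjusted p = 8.89e-07, and adjusted p = 0.21 with an estimated correlation), with FAP, a protease of activated fibroblasts, at log2 1.85 (SE 0.34), COL1A1 at 1.75 (SE 0.49), COL1A2 at 1.20 (SE 0.34) and THY1 at 1.60 (SE 0.37). CEMIP, a protein that breaks down hyaluronan, rose by log2 3.71 (SE 0.81). Endothelial markers rose in 4 of 9 cases (5 adjusted over the list alone, median 0.70, adjusted p = 0.000108, and adjusted p = 0.21 with an estimated correlation), among them SELE at log2 2.12 (SE 0.64), MADCAM1, which guides lymphocytes into gut mucosa, at 1.52 (SE 0.44), PECAM1 at 0.94 (SE 0.27) and SELP at 0.59 (SE 0.16).

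Genes of TH1 cells and of the response to interferon gamma, together called interferon gamma genes here, rose in 7 of 14 cases (9 adjusted over the list alone, median 0.70, adjusted p = 1.03e-06, and adjusted p = 0.21 with an estimated correlation). These included CXCL11 at log2 2.84 (SE 0.74), CXCL9 at 1.83 (SE 0.58) and GBP1 at 1.55 (SE 0.43). Genes of MHC class II antigen presentation rose in 5 of 8 cases (7 adjusted over the list alone, median 1.23, adjusted p = 1.02e-05, and adjusted p = 0.21 with an estimated correlation), with HLA-DRA at log2 1.73 (SE 0.54), their master regulator CIITA at 1.5 (SE 0.44) and HLA-DMA at 1.11 (SE 0.29). The TH17 and TH22 list was not called (adjusted p = 0.0758, median 0.30), and its members went both ways. It was called upward with the slide as a random block (adjusted p = 0.0354) and as a fixed block (adjusted p = 0.0439), against 0.0354 to 0.71 over the settings run for lists. IL23A, a subunit of the cytokine IL-23, rose by log2 1.47 (SE 0.41) and its receptor gene IL23R by 0.59 (SE 0.16), while IL17A fell by 0.88 (SE 0.29, adjusted p = 0.0391). IL17A and IL23R turned direction within slide 5 (0.089 and −0.37) and under a fixed slide block (0.15 and −0.35). IL26 had a log2 fold change of 0.99 (SE 0.35, adjusted p = 0.059). T cell markers (adjusted p = 0.131), B and plasma cell markers (0.121), regulatory T cell genes (0.119) and monocyte and macrophage markers (0.901) were not called. A fixed slide block called the T cell markers upward (adjusted p = 0.0439, against 0.0439 to 0.548 over the settings run for lists).

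Genes of absorptive colonocytes fell. Of 15 colonocyte markers, 9 fell (11 adjusted over the list alone) and all 15 were lower, with a median log2 fold change of −2.77 (adjusted p = 4.8e-07, and adjusted p = 0.254 with an estimated correlation). PCK1, an enzyme of glucose synthesis, fell by 5.31 on the log2 scale (SE 1.00). Its level lay from −4.98 to −2.75 in the colonic CD active biopsies. In the ileal ones it lay from 1.59 to 3.74, against 2.99 ± 0.72 (SD) in CD normal mucosa. The sulfate carrier SLC26A2 (log2 −4.22, SE 1.04), the water channel AQP8 (−3.96, SE 1.24) and the carbonic anhydrase CA1 (−3.94, SE 0.99) fell too. So did GUCA2B (−4.21, SE 0.78) and GUCA2A (−3.69, SE 0.85), the precursors of uroguanylin and guanylin. Genes of fatty acid oxidation fell in 12 of 14 cases (13 adjusted over the list alone, median −1.0, adjusted p = 1.9e-08, and adjusted p = 0.21 with an estimated correlation). Among them were CPT1A, which admits fatty acids into mitochondria (−1.13, SE 0.26), ETFB (−0.999, SE 0.21) and HADHA (−0.88, SE 0.22). Of 12 genes of xenobiotic metabolism, 7 fell (8 adjusted over the list alone, median −1.35, adjusted p = 8.72e-07, and adjusted p = 0.21 with an estimated correlation). They included UGT2A3 (−5.70, SE 1.05), the drug pump ABCB1 (−2.41, SE 0.55), EPHX2 (−1.62, SE 0.26) and the pregnane X receptor gene NR1I2 (−1.07, SE 0.24). The level of EPHX2 lay from 0.021 to 1.463 in colonic CD active biopsies and from 2.085 to 3.696 in ileal ones, against 2.77 ± 0.49 (SD) in CD normal mucosa. For PCK1 and EPHX2 this split rests on the segment labels. Of the 4 biopsies labelled ileal, 1 lay within the colonic range on the small-intestinal enterocyte list. Outside the lists, the noncoding CDKN2B-AS1 (−5.31, SE 1.01) and DPP10-AS1 (−4.47, SE 1.42), the lipase-related PNLIPRP2 (−4.60, SE 0.92), the magnesium channel TRPM6 (−4.13, SE 0.98), BMP3 (−3.99, SE 0.99) and PDE6A (−3.97, SE 0.97) fell.

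Other epithelial markers went both ways. Stem cell markers rose as a list with 2 of 6 called (2 adjusted over the list alone, median 0.53, adjusted p = 0.0356, and adjusted p = 0.288 with an estimated correlation), namely OLFM4 at log2 2.63 (SE 0.74) and LGR5 at 0.67 (SE 0.22). Of 10 proliferation genes, 4 rose (6 adjusted over the list alone, median 0.63, adjusted p = 2.84e-05, and adjusted p = 0.21 with an estimated correlation), among them MCM2 at log2 0.62 (SE 0.12), MKI67 at 0.66 (SE 0.15), RRM2 at 0.84 (SE 0.24) and CDK1 at 0.94 (SE 0.32). MKI67 turned direction within slide 5 (−0.23) and under a fixed slide block (−0.24). Goblet cell markers were not called as a list (adjusted p = 0.273), while FCGBP (−0.63, SE 0.20) and BEST2 (−2.52, SE 0.83) fell. Junction genes went both ways, with 2 of 9 up and 6 down, a median of −0.63, a mean of −0.06 and no call (adjusted p = 0.0771). The junction list was called downward among brighter genes (adjusted p = 0.00511, against 0.00511 to 0.288 over the settings run for lists). The pore-forming CLDN2 rose by log2 3.96 (SE 0.96) and CLDN1 by 2.47 (SE 0.57), while OCLN (−1.01, SE 0.23) and CDH1, which encodes E-cadherin (−0.86, SE 0.21), fell. The unfolded protein response list rose with 1 of 10 members called, XBP1 at log2 0.73 (SE 0.25), and 4 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.384 with an estimated correlation). The small-intestinal enterocyte list fell with 1 of 16 members called, ANPEP (−2.58, SE 0.87), and none adjusted over the list alone (median −1.09, adjusted p = 0.0356, and adjusted p = 0.548 with an estimated correlation). A fixed slide block ended that call (adjusted p = 0.335, against 0.00301 to 0.548 over the settings run for lists), within slide 5 the median was 0.70 with 6 of 16 members of the same sign, and 1 ileal biopsy lay within the colonic range on this list. The lists not called, 17 in number, had adjusted p between 0.0758 and 0.901, among them TH2 genes, type 1 interferon genes and the markers of mast, red, smooth muscle, nerve, Paneth and enteroendocrine cells, and genes of distal patterning and of handling.

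Within slide 5, the 5 CD active arrays and the single CD normal array gave the same sign as the fit for 94.1% of the genes that fell (median log2 difference −0.70) and for 55.9% of those that rose (median 0.12), against 58.0% of the genes not called. With a fixed slide block, which rests on the same single normal array, 4 genes were called, none of them among the 2550, and 16 of the 32 lists. By fry, 13 of the 15 lists that camera called passed, all but the unfolded protein response (adjusted p = 0.0754) and small-intestinal lists (0.174), and the junction list passed too (0.00672). Of the 73 called genes among the 74 checked, 47 lost the call when some biopsy was left out, 44 of them without CD active replicate 7 and 33 without CD active replicate 2. Among those 47 were SAA1 (adjusted p up to 0.0674), REG1A (up to 0.117), IL23A (up to 0.13) and IL17A (up to 0.147), whereas MMP9 and PCK1 kept the call (adjusted p up to 0.0118 and 0.0106), although both turned direction with the donor as a fixed replicate block (−0.015 and 0.12).

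In UC, the same comparison was made between active and normal mucosa. SAA1 was higher by log2 2.72 (SE 1.07) in active mucosa, above the UC normal mean in 6 of 7 biopsies, and did not pass the test over all genes (adjusted p = 0.128). DUOX2 (log2 3.04, SE 0.94, adjusted p = 0.0515) and DUOXA2 (3.69, SE 1.27, adjusted p = 0.0789) likewise did not pass. As a list, the acute-phase and antimicrobial genes rose, since all 19 were higher with a median of 1.62, although none was called singly, over all genes or adjusted over the list alone (camera adjusted p = 5.72e-05, and adjusted p = 0.885 with an estimated correlation). Collagen and fibroblast genes rose as a list, with 1 of 11 called (4 adjusted over the list alone, median 0.59, adjusted p = 0.00121, and adjusted p = 0.885 with an estimated correlation). COL1A2 rose by log2 1.27 (SE 0.34), and COL1A1 had a value of 1.46 (SE 0.48, adjusted p = 0.0638). Type 1 interferon genes rose as a list without a single call over all genes (2 adjusted over the list alone, median 0.42, adjusted p = 0.00728, and adjusted p = 0.885 with an estimated correlation), with MX1 at 0.57 (SE 0.20, adjusted p = 0.0797) and MX2 at 0.68 (SE 0.23, adjusted p = 0.0695).

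Plasma cell genes DERL3 and SDC1 rose in UC active mucosa by log2 0.58 (SE 0.13) and 0.63 (SE 0.17), and GBP2, an interferon-induced GTPase, by 1.11 (SE 0.29), each above the UC normal mean in 7 of 7 biopsies. SDC1 and GBP2 turned direction with the donor as a fixed replicate block (−0.16 and −0.22). The B and plasma cell list was not called, with 6 of 11 members higher (median 0.12, adjusted p = 0.227). CD3E, a T cell receptor subunit (log2 −1.42, SE 0.38), ITGAM, an integrin of myeloid cells (−0.88, SE 0.26), and ELAVL4, a neuronal RNA-binding protein (−1.07, SE 0.32), fell. They do not stand for their cell types, as 7 of 10 T cell markers were higher (median 0.21, adjusted p = 0.835) and the monocyte and macrophage list was not called (adjusted p = 0.738). Among the largest changes, the connexin gene GJA10 rose by log2 3.15 (SE 0.84) and WNT7B by 2.19 (SE 0.54), and SOX18 was at least 3.2-fold higher. SEC14L5 fell by 3.63 (SE 0.72), and MYO1H was at least 6.5-fold lower. None of the 3 called lists passed the self-contained test fry (adjusted p = 0.309 each), and type 1 interferon genes lost the call among brighter genes (adjusted p = 0.0503). The other 29 lists were not called by camera (adjusted p from 0.191 to 0.893), including the colonocyte markers (median −0.98), neutrophil markers (median 0.48) and the TH17 and TH22 list (median 0.18).

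In all, 442 genes rose and 567 fell in UC active mucosa, and 75.3% of the rises but 24.3% of the falls had a mean signal above the median gene. No slide held both groups, a fit with the slide as a fixed block could not be had, and with the slide as a random block none rose and 1 fell, so the slide and the group cannot be told apart in UC. The protocol name also differed between 6 of the 7 UC active arrays and all UC normal arrays. Without UC active replicate 6 the count was 517, and 9 of the 17 called genes among those checked lost the call without some biopsy.

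**Figure D2:**
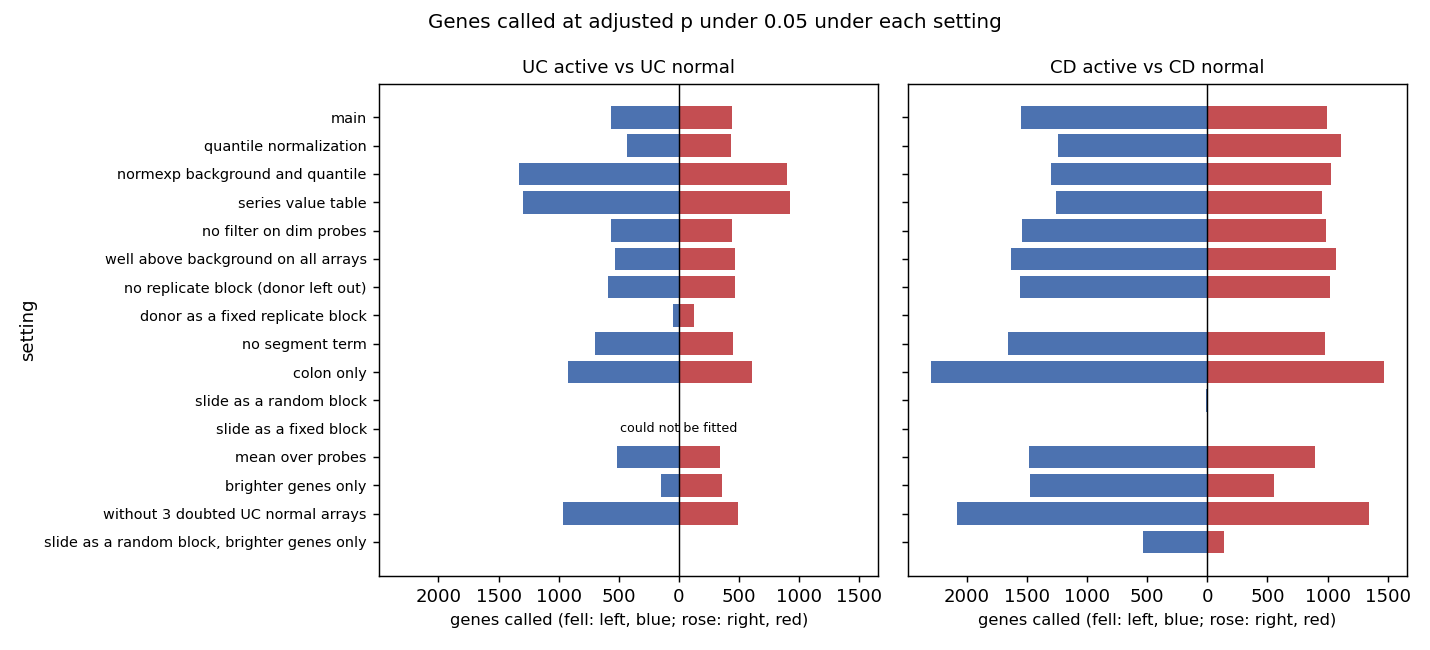
Number of genes called at an adjusted p under 0.05 (x axis, falls to the left and rises to the right) under each setting (y axis) for active against normal mucosa in UC (left) and CD (right). With a random slide block the counts are 1 in UC and 17 in CD, against 1009 and 2550 in the fit with the donor as a random block.

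**Figure D3:**
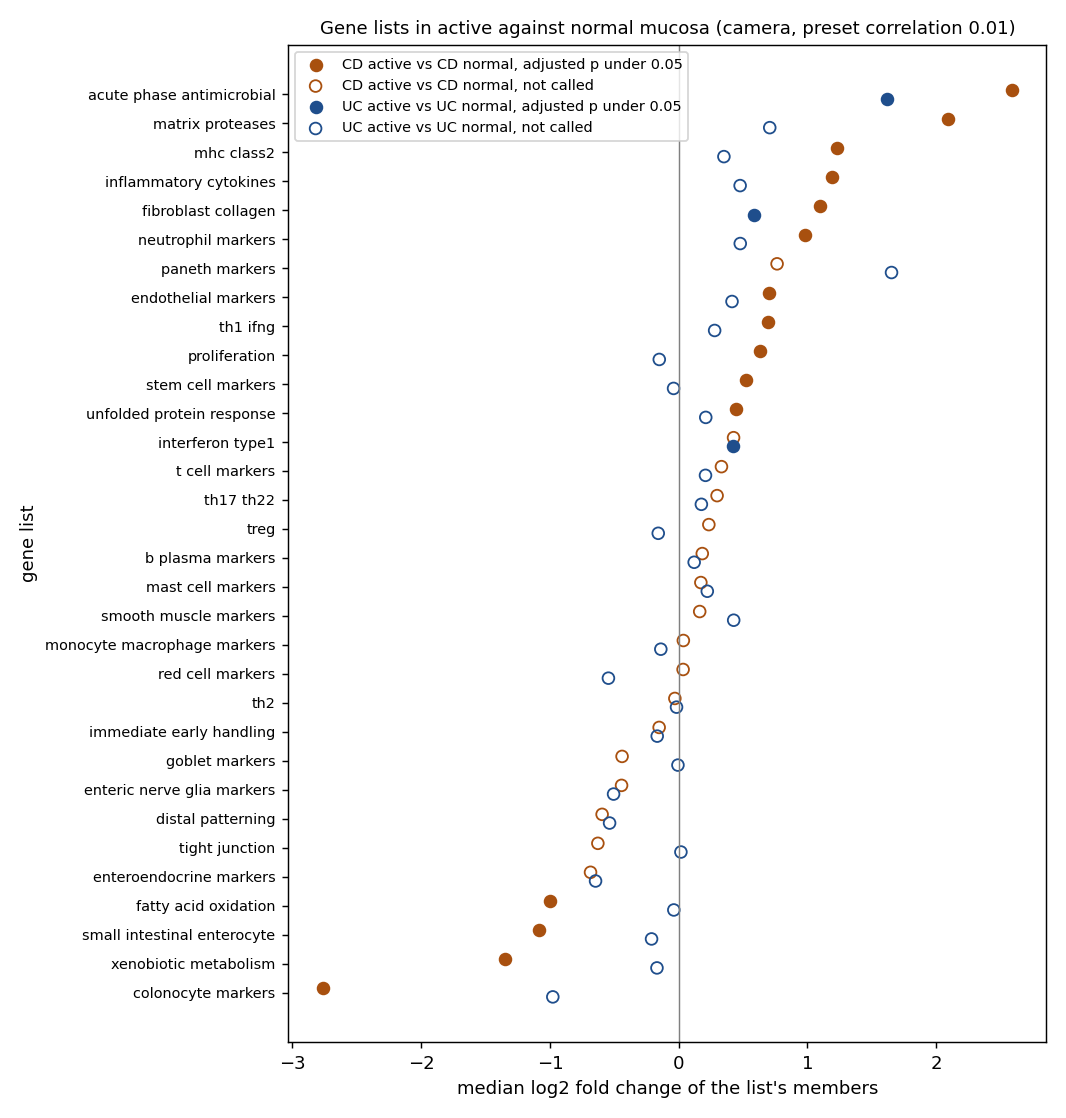
Median log2 fold change (x axis) of the members of the 32 gene lists (y axis) in active against normal mucosa, for CD (brown) and UC (blue). Filled points have a camera adjusted p under 0.05 at the preset correlation, which holds for 15 lists in CD and 3 in UC, and for 0 lists in either disease with an estimated correlation.

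The difference between the diseases was tested directly, as the change from normal to active mucosa in UC minus that in CD. It passed for 2043 genes, 1015 with the more positive change in UC and 1028 with the more positive change in CD. SAA1 did not differ by this test (log2 difference −1.59, SE 1.50, adjusted p = 0.547). Genes of the absorptive lining had the more positive change in UC as lists. The median difference was 2.13 over 15 colonocyte markers with 1 called (3 adjusted over the list alone, adjusted p = 0.00323, and adjusted p = 0.88 with an estimated correlation), 0.83 over 14 genes of fatty acid oxidation with 3 called (9 adjusted over the list alone, adjusted p = 0.00036, and adjusted p = 0.88 with an estimated correlation), and 1.4 over 12 genes of xenobiotic metabolism with 4 called (6 adjusted over the list alone, adjusted p = 0.00194, and adjusted p = 0.88 with an estimated correlation). Single genes were CPT1A with a difference of 1.58 (SE 0.36), NR1I2 with 1.53 (SE 0.33), EPHX2 with 1.5 (SE 0.36), SULT1B1 with 1.35 (SE 0.30), ETFB with 1.18 (SE 0.29), CA4 with 2.47 (SE 0.80) and the junction gene CLDN4 with 1.00 (SE 0.22).

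Proliferation genes moved the other way, with a median difference of −0.70 and 3 of 10 called (4 adjusted over the list alone, adjusted p = 0.00036, and adjusted p = 0.88 with an estimated correlation), namely MCM2 at −0.79 (SE 0.17), MKI67 at −0.93 (SE 0.21) and RRM2 at −1.41 (SE 0.33). Matrix proteases (median −1.64, adjusted p = 0.0257), inflammatory cytokines (−1.19, adjusted p = 0.0266), interferon gamma genes (−0.78, adjusted p = 0.0266) and MHC class II genes (−0.93, adjusted p = 0.0266) were also more positive in CD, and with an estimated correlation their adjusted p lay between 0.88 and 0.884. MMP9 differed by −2.19 (SE 0.51), IL2RA by −1.54 (SE 0.40), IL23R by −1.05 (SE 0.22) and IL17A by 1.56 (SE 0.40), and CEMIP by −3.60 (SE 1.12). Among brighter genes the matrix protease (adjusted p = 0.0572), cytokine (0.55) and interferon gamma lists (0.476) lost the call. By fry, 2 of these 8 lists passed, xenobiotic metabolism (adjusted p = 0.0288) and proliferation (0.0212). A random slide block gave 12 genes more positive in UC and 45 more positive in CD, and CA4, CEMIP, LCE5A and SOX1 lost the call when some single biopsy was left out.

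Active and inactive UC mucosa were compared next. SAA1 was higher by log2 3.04 (SE 1.08) in active mucosa without passing the test (adjusted p = 0.0733). DUOX2 rose by 2.94 (SE 0.95, adjusted p = 0.0499) and LCN2, an antimicrobial iron-binding protein, by 2.64 (SE 0.83). Acute-phase and antimicrobial genes rose as a list with 3 of 19 called (9 adjusted over the list alone, median 1.91, adjusted p = 0.000373, and adjusted p = 0.766 with an estimated correlation), and neutrophil markers with 2 of 9 (4 adjusted over the list alone, median 1.26, adjusted p = 0.00825, and adjusted p = 0.766 with an estimated correlation), among them CXCR1 at log2 1.52 (SE 0.42) and FPR2 at 1.55 (SE 0.45). IL17A rose by 1.47 (SE 0.28, adjusted p = 0.00214) and CCR6, the receptor for CCL20, by 0.63 (SE 0.19). TH2 genes rose with 2 of 8 called (3 adjusted over the list alone, median 0.62, adjusted p = 0.0406, and adjusted p = 0.766 with an estimated correlation), with IL13 at least 4.0-fold higher and the IL-33 receptor gene IL1RL1 up by 1.87 (SE 0.47). Mast cell markers rose with 1 of 6 called, GATA2 at 1.42 (SE 0.42), and cytokines with 1 of 15, while colonocyte markers (none of 15 called, median −1.03), fatty acid oxidation (1 of 14, ETFA at −0.56, SE 0.17) and proliferation (1 of 10, MCM2 at −0.45, SE 0.12) fell as lists. These 5 lists had adjusted p from 0.0152 to 0.0421, and adjusted p = 0.766 with an estimated correlation. Of the 8 lists, the TH2 genes passed by fry (adjusted p = 0.0408), and cytokines, colonocyte markers and fatty acid oxidation lost the call with the slide as a random block. Among brighter genes 7 lists were called, all upward, so none of the falling lists kept its call. In all 1240 genes rose and 261 fell.

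The share of rises was 82.6%, and it was 44.9% under quantile normalization, which moved the median of all genes from 0.008 to −0.095. Within slide 2, which held all inactive arrays and 1 active array, 80.1% of the rises and 99.2% of the falls had the same sign, against 64.0% of genes not called, and with the slide as a fixed block 207 genes and none of the lists were called. Under that block the median of the colonocyte markers turned to 0.45 (0.55 within slide 2, with 4 of 15 of the same sign) and that of the cytokines to −0.10. The median of the neutrophil markers was −0.020 (0.020 within slide 2, with 5 of 9 of the same sign) and that of the acute-phase list 0.33, and FPR2 (−0.16), CCR6 (−0.33) and CXCR1 turned direction. These values rest on the single active array of slide 2, whose own level enters every gene. They therefore cannot decide on a slide effect. In that biopsy SAA1 lay at −4.39, against −4.82 ± 2.14 (SD) in UC inactive mucosa. PCK1 lay at 4.03, the highest of its group, while DUOX2 lay at 2.16, above the UC inactive mean of 0.24. Of the 23 called genes among the 24 checked, 16 lost the call when some biopsy was left out, 15 of them without UC active replicate 5 and 14 without UC active replicate 1. Among them were DUOX2 (adjusted p up to 0.125) and LCN2 (up to 0.119). The count of called genes fell to 609 without UC active replicate 1, and to between 762 and 934 without UC active replicate 5 or 6 or UC inactive replicate 2, 3 or 6.

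UC inactive mucosa differed from UC normal mucosa in 1029 genes that rose and 2275 that fell. SAA1 did not differ (log2 −0.32, SE 1.05, adjusted p = 0.879), and none of the 32 lists was called (adjusted p from 0.0779 to 0.988). Type 1 interferon genes were called upward with the slide as a random block (adjusted p = 0.034, against 0.034 to 0.959 over the settings run for lists). Among brighter genes 2 lists were called, both downward. By fry, regulatory T cell genes (adjusted p = 0.0376) and nerve and glia markers (0.0197) passed, both lower. Single immune genes fell. These were CD3E (log2 −1.95, SE 0.37), the neutrophil chemokine receptor gene CXCR1 (−2.04, SE 0.41), ITGAM (−1.25, SE 0.26), IL6 (−1.41, SE 0.25) and IL10 (−0.81, SE 0.17). OAS1, an antiviral enzyme, rose by 0.77 (SE 0.23). The largest falls were in LCE5A (−6.12, SE 0.83), TRIM49 (−4.54, SE 0.69) and PCDHB18P (−4.42, SE 0.72), and 12.7% of the falls had a mean signal above the median gene. Quantile normalization moved the median of all genes from −0.009 to 0.114 and gave 1497 rises and 1038 falls, no slide held both groups, and with the slide as a random block 17 rose and 210 fell.

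In CD, the 2 inactive biopsies were compared with the 10 normal ones. SAA1 had a log2 fold change of 2.19 (SE 1.57, adjusted p = 0.845) and DUOX2 of 2.09 (SE 1.38, adjusted p = 0.84), with both inactive biopsies above the CD normal mean for both genes. By limma no gene was called, and 1071 of 19570 had an unadjusted p under 0.05. Without CD normal replicate 7, 163 were called. That array was the only CD normal one on slide 5, which held both CD inactive arrays. Without it the groups shared no slide, so slide and group cannot be told apart in that count. Genes of fatty acid oxidation were lower as a list, with 14 of 14 lower and none called singly (median −0.45, adjusted p = 0.0268, and adjusted p = 0.98 with an estimated correlation), for example ETFB at −0.46 (SE 0.30) and HADHB at −0.35 (SE 0.24). The call ended with the slide as a fixed block (adjusted p = 0.208) and among brighter genes (adjusted p = 0.0975), against 0.00539 to 0.98 over the settings run for lists. Within slide 5, with its single normal array, 9 of 14 kept their sign, and HADHB was at 0.019. By fry the list did not pass (adjusted p = 0.946). The acute-phase list, higher in 18 of 19 members and not called (adjusted p = 0.0794), was called upward with the slide as a random block, as a fixed block and among brighter genes (adjusted p from 0.0059 to 0.98 over the settings run for lists). MHC class II genes (from 0.00046 to 0.98) and proliferation genes (from 0.00657 to 0.98) were called upward in the same 3 settings. Regulatory T cell and collagen genes were called upward with the slide as a random block, and the latter among brighter genes too.

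Mucosa labelled normal was compared between the diseases. SAA1 did not differ (log2 −0.31, SE 1.02, adjusted p = 0.903). CD86, a costimulatory ligand of antigen-presenting cells, was higher in UC by log2 3.65 (SE 0.89), CD3E by 1.49 (SE 0.36) and the stem cell marker EPHB2 by 0.53 (SE 0.15), and IL17A was lower in UC, with a log2 difference of −0.99 (SE 0.27). The early response gene JUNB, which handling can induce, was higher in UC by 0.74 (SE 0.16), and the list of such genes was not called (median 0.53, adjusted p = 0.171). That list was called upward with the slide as a random block (adjusted p = 0.0487, against 0.0487 to 0.93 over the settings run for lists). In all 646 genes were higher and 397 lower in UC normal mucosa, and none of the lists was called (adjusted p from 0.171 to 0.83). Without the 3 UC normal arrays that correlated least with the value table, 957 genes were higher and 179 lower. Of the 1043 genes called, 504 stayed called there, and 6 of the 10 genes checked lost the call. The count of 1043 fell to 600 without CD normal replicate 6, to 600 without CD normal replicate 10 and to 670 without UC normal replicate 5. These groups shared no slide, and with the slide as a random block limma called none (1222 genes had an unadjusted p under 0.05), so slide and disease cannot be told apart here.

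Ileal biopsies were compared with those of the distal colon. Most ileal biopsies came from active CD mucosa, so these differences rest largely on inflamed ileum. They cannot be read as differences between regions of normal mucosa. Of 16 small-intestinal enterocyte genes, 14 rose (16 adjusted over the list alone, median 4.53, adjusted p = 4.52e-29, and adjusted p = 0.00695 with an estimated correlation). Genes of fat absorption showed the largest rises, with APOB at log2 9.42 (SE 1.08), APOA4 at 9.21 (SE 1.03) and MTTP at 8.94 (SE 1.10). Xenobiotic metabolism rose in 9 of 12 genes (11 adjusted over the list alone, median 1.64, adjusted p = 3.66e-09, and adjusted p = 0.079 with an estimated correlation), with UGT2A3 at 5.95 (SE 1.21) and CYP3A4 at 1.67 (SE 0.29). Genes that fell included NOX1, an oxidase of the colonic epithelium, at log2 −4.75 (SE 0.59), CA12 at −5.0 (SE 0.76), CLCA4 at −4.47 (SE 0.87) and the patterning gene HOXA13 at −4.27 (SE 1.05). The colonocyte list was not called, with 2 of 15 up and 6 down (adjusted p = 0.0605). It was called downward with the slide as a random block (adjusted p = 0.0266) and as a fixed block (adjusted p = 0.00518), against 0.00518 to 0.646 over the settings run for lists. Proliferation genes fell in 6 of 10 cases (7 adjusted over the list alone, median −0.84, adjusted p = 0.000189, and adjusted p = 0.391 with an estimated correlation), with AURKA at −1.11 (SE 0.25). The other 9 called lists had adjusted p from 0.000155 to 0.0458, and adjusted p = 0.583 with an estimated correlation. They were, with their medians, fatty acid oxidation (0.58), MHC class II (1.25), type 1 interferon (0.34), interferon gamma (0.39) and Paneth cell genes (3.06) on the rising side, and collagen (−0.80), B and plasma cell (−0.84), distal patterning (−1.19) and matrix protease genes (−1.0) on the falling side. Matrix protease genes lost the call with the slide as a random block (adjusted p = 0.0957) and as a fixed block (adjusted p = 0.465), against 0.0458 to 0.583 over the settings run for lists. Collagen genes lost it with a fixed block (adjusted p = 0.145, against 0.00211 to 0.583 over the settings run for lists), under which T cell markers gained one. Among brighter genes 6 lists were called, and interferon, B and plasma cell, matrix protease, collagen and Paneth cell genes lost the call. By fry, 5 of the 12 called lists passed. SAA1 did not differ (log2 −1.15, SE 1.26, adjusted p = 0.659). In all 1054 genes rose and 1215 fell. With the donor as a fixed replicate block 0 genes were called, although 89.6% of the called genes kept their sign. The count of 2269 fell to 1089 without CD normal replicate 2 and to 1225 without CD active replicate 3. CLCA4 (adjusted p up to 0.0741) and HOXA13 (up to 0.0829) lost the call without CD normal replicate 2.

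On the mean of the small-intestinal list, 3 of the 4 ileal biopsies lay at 3.31 to 4.31 and 1 lay within the range of the 37 colonic biopsies, −3.79 to −2.18. Without that biopsy APOB differed by log2 12.00 (SE 0.38), and 3337 genes were called.

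Between the proximal and the distal colon, limma called no gene, and 542 of 19570 had an unadjusted p under 0.05. SAA1 had a value of 0.45 (SE 0.73, adjusted p = 0.998). The distal marker PRAC1 was at −2.12 (SE 0.66, adjusted p = 0.998), HOXB13 at −2.06 (SE 0.86, adjusted p = 0.998) and the hormone gene INSL5 at −1.51 (SE 0.56, adjusted p = 0.998). Lists that were lower in the proximal colon were the early response genes (median −0.53, adjusted p = 2.53e-08, and adjusted p = 0.145 with an estimated correlation), enteroendocrine markers (median −0.62, adjusted p = 7.96e-06, and adjusted p = 0.145 with an estimated correlation), B and plasma cell markers (median −0.30, adjusted p = 0.000195, and adjusted p = 0.199 with an estimated correlation) and distal patterning genes (median −0.26, adjusted p = 0.00707, and adjusted p = 0.255 with an estimated correlation). Collagen (−0.17) and unfolded protein response genes (−0.11) were lower and fatty acid oxidation (0.16) and proliferation genes (0.12) higher as lists, with adjusted p from 0.00932 to 0.0482, and adjusted p = 0.856 with an estimated correlation. Collagen and proliferation genes lost the call with the slide as a random block and as a fixed block, and fatty acid oxidation lost it with the fixed block. None of the 8 called lists passed by fry.

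Across 26 donors, with group and segment removed, SAA1 was positively correlated with 5 of the 12 genes tested, of which 3 are epithelial defence genes. Pearson's r was 0.840 for NOS2, which makes nitric oxide (rho 0.802, adjusted p = 0.00012 by permutation, from the smallest p that 100000 permutations can give, 1e-05). It was 0.728 for LCN2 (rho 0.713, adjusted p = 0.00018), 0.696 for DUOX2 (rho 0.662, adjusted p = 0.00032), 0.520 for CCL20, a chemokine for CCR6-bearing cells (rho 0.525, adjusted p = 0.0196), and 0.501 for IFNG (rho 0.445, adjusted p = 0.0215). IL23A (r 0.426, rho 0.443) and IL26 (r 0.421, rho 0.467) had an adjusted p of 0.0556 for r and 0.0407 for rho. Lower values were found for IL22 (r 0.329, rho 0.400), FOXP3 (r 0.342, rho 0.372), IL17A (r 0.164, rho 0.145) and IL17F (r −0.325, rho −0.378), with adjusted p from 0.126 to 0.424 for r. Whether the r of epithelial genes differs from that of cytokines was not tested.

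Without the 2 donors farthest from the median of SAA1, r was 0.728 for NOS2, 0.638 for LCN2, 0.583 for DUOX2, 0.528 for CCL20 and 0.489 for IFNG, each still past the threshold, and 0.482 for IL22 (adjusted p = 0.0318). With the slide also removed, NOS2 (r 0.805), LCN2 (r 0.728) and DUOX2 (r 0.701) passed, and CCL20 (r 0.447, adjusted p = 0.065) and IFNG (r 0.387, adjusted p = 0.101) did not. Within the 14 UC donors r was 0.879 for NOS2, 0.867 for LCN2, 0.850 for DUOX2 and −0.721 for IL17F (adjusted p = 0.0108). Within the 12 CD donors it was 0.676 for NOS2 (adjusted p = 0.0791), 0.365 for DUOX2 (adjusted p = 0.673) and 0.242 for LCN2 (adjusted p = 0.765), and 0.877 for IL23A (adjusted p = 0.00456). The difference in r between the diseases was not tested.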

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

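The tests of explanations in this part were chosen after the results they measure had been seen, while the splits of the biopsies had been planned before.

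Among groups of 7 to 10 biopsies, 1 value stood apart in 4 of 50 groups of values examined, where chance gives about 1 in 20. In UC inactive mucosa 1 biopsy had an SAA1 level separated from the others by 0.672 of the range of the group. The same biopsy stood apart for MMP9 by 0.682 of the range, and it was the highest of its group for DUOX2 (4.70) and REG1A (7.61). The UC active biopsy of the same donor was the lowest of its own group for SAA1 (−4.71) and DUOX2 (0.31). The states of both were taken as labelled, a swap of the labels was not tested, and no fit left both biopsies out. For the share of spots well above background, 1 array lay apart by 0.623 of the range in the CD active group and by 0.609 in the UC active group.

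The change from normal to active mucosa differed between UC and CD for 2043 genes. Of 100 splits, 1, the real one, called as many, and the highest other called 42. The splits shuffled active and normal labels within each disease. They therefore speak to a change in either disease and cannot decide whether the changes differ. With the slide as a random block 57 genes were called, and the groups lay largely on separate slides. Genes with a more positive change in UC were SOX1 (4.12), RIPPLY3 (4.04), SSX8P (3.96), CA4 (2.47), ABCB1 (2.32), CPT1A (1.58), IL17A (1.56), NR1I2 (1.53), EPHX2 (1.5), SULT1B1 (1.35), ETFB (1.18), CLDN4 (1.00), CDH1 (0.99), FCGBP (0.95) and HADHB (0.79), on the log2 scale. Genes with a more positive change in CD were LCE5A (−4.35), EDDM3B (−4.12), CEMIP (−3.60), PABPC5 (−3.56), RPRML (−3.17), CLDN1 (−2.62), MMP9 (−2.19), CD3E (−1.91), FAP (−1.67), IL2RA (−1.54), RRM2 (−1.41), IL6 (−1.39), IL23R (−1.05), MKI67 (−0.93) and MCM2 (−0.79). The lists that differed, with their median differences, were colonocyte markers (2.13), xenobiotic metabolism (1.4), fatty acid oxidation (0.83), matrix proteases (−1.64), inflammatory cytokines (−1.19), MHC class II (−0.93), interferon gamma genes (−0.78) and proliferation (−0.70). None of these 8 passed with an estimated correlation (adjusted p from 0.88 to 0.884), and 2 passed by fry. EDDM3B was above background on none of the 17 arrays of one side of this contrast, which makes its difference a value near the floor.

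In UC active mucosa most of the genes that fell had dim signal, and 201 of them rose in CD, against 28.9 expected of independent lists. The other overlaps lay below the expected numbers: 19 genes rose in both diseases (22.6 expected), 11 fell in both (44.9), and 20 rose in UC and fell in CD (35.0). The 3 UC normal arrays that correlated least with the value table are not the whole cause, as 422 of the 567 falls were called without them, although of all 1009 rises and falls 590 were. Of the genes that fell in UC, 22.4% had the same sign in CD. This share cannot decide on a response to inflammation shared with CD, since in both diseases the groups lay largely on separate slides. The 201 genes above are part of the same counts, so this share is not separate from the overlap. The slide of the UC normal arrays stays open: with the slide as a random block 1 fall was called, and since no slide held both groups, slide and inflammation cannot be told apart for these genes. A difference between the diseases also stays open, untested apart from the slide.

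In CD active mucosa, colonocyte, fatty acid oxidation and xenobiotic genes fell together, 28 of 41 members in the full set of biopsies. Ileal biopsies are not the cause, since 36 of the 41 fell among colonic biopsies alone. A lower share of epithelium is argued against as the whole cause, because stem cell markers, which are epithelial too, had a median of 0.53 with 2 of 6 up and none down, although that list lost its call with an estimated correlation (adjusted p = 0.288) and among brighter genes (adjusted p = 0.0684), against 0.00507 to 0.288 over the settings run for lists. A lower share as part of the cause stays open, as CDH1 (−0.86) and OCLN (−1.01) fell, goblet markers were lower in 9 of 12 cases and enteroendocrine markers in 8 of 9, and fibroblast and endothelial markers were higher in 11 of 11 and 9 of 9. A gain in the cells that carry the stem cell markers stays open too. For the slide, 40 of the 41 members had the same sign within slide 5, but that slide held a single normal array, so this test cannot decide it. A loss of mature absorptive cells or of their program with inflammation may contribute, as a hypothesis that stays open beside the slide and the share of epithelium.

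Genes that rose in CD active mucosa were also compared within slide 5, against its single normal array. There, 51.9% of the 570 dimmer rises and 61.1% of the 429 brighter rises had the same sign, against 58.0% of the genes not called. Such values could come from a slide effect on many of the rises, and the level of that single array, which enters every gene, keeps this open for both sets, so slide and inflammation cannot be told apart for them. The gene lists that rose are a part of these genes, and 16 of the 32 lists, 13 of them upward, were called with the slide as a fixed block. That block compares the groups only within slide 5, so these calls rest on the same single normal array and cannot decide it.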

How the results depend on the processing

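The alternatives added after the data were seen are the brighter genes only, the slide as a random block among these, the fit without 3 UC normal arrays and the differences within a slide, and all others were planned. Direction was stable under scaling and filters: of the called genes, at least 96.8% kept their sign in every comparison under quantile normalization, normexp, the value table and both probe filters. Calls were less stable. For UC active vs UC inactive, 551 of the 1501 genes stayed called under quantile normalization, 515 under normexp and 484 under the value table. Each of these settings ended the call for 12 of the 24 genes checked there. The number of calls depends on how slide and donor enter the fit, and the cause of each change listed here was not tested. An exception is the fold threshold, which lowers counts by construction. Signal over background, from 84.9% to 98.6% of spots per array, limits what can be said of dim genes. With the donor as a fixed replicate block the standard errors grew (median 0.61 against 0.24 in CD, 0.50 against 0.23 in UC). The CD estimate for active against normal mucosa then equals the difference within 1 donor, whose biopsies are both ileal. UC normal against CD normal could not be fitted with the donor or the slide as a fixed block, and UC active or UC inactive against UC normal and the difference between the diseases could not be fitted with the slide as a fixed block.

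Gene counts that left the range within 1.5 times of the reported count were as follows. For UC active vs UC normal (1009), normexp gave 2227, the value table gave 2223, and colon only 1525. The donor as a fixed replicate block gave 174, the slide as a random block 1, the brighter genes 505, the brighter genes with the slide as a random block 2, and the fold threshold 278. For CD active vs CD normal (2550), the donor as a fixed replicate block gave 2, the slide as a random block 17, the slide as a fixed block 4, the brighter genes with the slide as a random block 676, and the fold threshold 790. For UC inactive vs UC normal (3304), normexp gave 2128, the value table gave 2125, and the donor as a fixed replicate block 764. The slide as a random block gave 227, the brighter genes 979, these with the slide as a random block 88, and the fold threshold 1776. For UC active vs UC inactive (1501), quantile normalization gave 855, normexp 809, the value table gave 731, and signal well above background on all arrays 981. The donor as a fixed replicate block gave 0, the slide as a random block 156 and as a fixed block 207, the brighter genes 322, these with the slide as a random block 28, the fit without 3 UC normal arrays 2358, and the fold threshold 939. For CD inactive vs CD normal (0), normexp gave 2, the donor as a fixed replicate block 2 and the slide as a fixed block 2.

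For active minus normal in UC vs in CD (2043), normexp gave 3077, the donor as a fixed replicate block 67, the slide as a random block 57, the brighter genes with the slide as a random block 200, the fit without 3 UC normal arrays 3766, and the fold threshold 1014. For UC normal vs CD normal (1043), normexp gave 3219, the value table gave 3188, the slide as a random block 0, the brighter genes 305, these with the slide as a random block 0, and the fold threshold 424. For ileum vs distal colon (2269), the donor as a fixed replicate block gave 0 and the fold threshold 1154. Proximal colon vs distal colon gave 0 under every alternative run.

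Leaving out 1 biopsy gave counts from 517 (without UC active replicate 6) to 1402 for UC active vs UC normal, from 897 (without CD active replicate 7) to 3404 for CD active vs CD normal, from 2395 to 3907 for UC inactive vs UC normal, and from 609 to 2152 for UC active vs UC inactive. In the last of these, the count moved by over 1.5 times without UC active replicate 1 (609), 5 (788) or 6 (762) and without UC inactive replicate 2 (797), 3 (934) or 6 (918). The range was from 0 to 163 (without CD normal replicate 7) for CD inactive vs CD normal, with 4 and 1 genes without CD inactive replicate 1 and replicate 2, where the lone sample left is assumed to vary like the other groups. It was from 1452 to 3021 for active minus normal in UC vs in CD, from 600 (without CD normal replicate 6, and also without replicate 10) to 1550 for UC normal vs CD normal, from 1089 (without CD normal replicate 2) to 3337 for ileum vs distal colon, and 0 for proximal colon vs distal colon. Without UC normal replicate 5, UC normal vs CD normal gave 670. CD normal replicate 7 was the only CD normal array on slide 5, which held both CD inactive arrays.

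Against 100 splits of the same biopsies, 2 gave as many genes for UC active vs UC normal, the real split among them. The highest other count was 1302, above the real one, and it was 36 among the splits that part as many donors. A random split can thus reach this count, though few did, and chance is not excluded. Only the real split gave as many genes for CD active vs CD normal (1 split, highest other 584), UC inactive vs UC normal (1, 597), UC active vs UC inactive (1, 1027), UC normal vs CD normal (1, 248) and ileum vs distal colon (1, 657). For proximal colon vs distal colon, with 0 genes called, all 100 splits give as many by construction (highest other 80), so this count decides nothing. The splits ignore the slide, so they do not speak to a slide effect.

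Gene list counts changed as follows. With an estimated correlation the number of lists called was 0 in place of 3 for UC active vs UC normal, 0 in place of 15 for CD active vs CD normal and 0 in place of 8 for UC active vs UC inactive. It was 0 in place of 1 for CD inactive vs CD normal, 0 in place of 8 for active minus normal in UC vs in CD, 1 in place of 12 for ileum vs distal colon and 0 in place of 8 for proximal colon vs distal colon. Under a random slide block it was 1 for UC inactive vs UC normal, 5 for UC active vs UC inactive, 6 for CD inactive vs CD normal and 1 for UC normal vs CD normal. Under a fixed slide block it was 0 for UC active vs UC inactive, 3 for CD inactive vs CD normal and 5 for proximal colon vs distal colon. Among the brighter genes it was 2 for UC inactive vs UC normal, 4 for CD inactive vs CD normal and 6 for ileum vs distal colon. In UC active vs UC inactive with the slide as a fixed block, the median of colonocyte_markers turned to 0.45, the median of inflammatory_cytokines to −0.10 and the median of neutrophil_markers to −0.020. The number of SAA1 correlations called was 3 in place of 5 with the slide also removed, 1 within CD donors and 8 pooled per biopsy.

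With the donor as a fixed replicate block, the estimate for CD active vs CD normal comes from 1 donor whose biopsies are both ileal. Single genes that turned direction did so mostly under that block. In CD active vs CD normal these were MMP3 (−0.34), DUOXA2 (−0.078), ABCA12 (−0.48), PCK1 (0.12), SLC26A2 (0.10), BMP3 (0.43), CA1 (0.89), HADHA (0.021), IDO1 (−0.71), CXCL1 (−1.25), CXCL3 (−0.01), MMP9 (−0.015), MMP7 (−0.91), CXCL9 (−1.06), CXCL11 (−0.62), GBP1 (−0.76), CIITA (−0.10), HLA-DRA (−0.35), HLA-DMA (−0.43), HLA-DOA (−0.57), COL1A1 (−0.58), COL1A2 (−0.35), THY1 (−0.24), PECAM1 (−0.088), MADCAM1 (−0.056), SELE (−0.78), FPR1 (−0.59), MNDA (−0.30) and BEST2 (0.059). In UC active vs UC normal they were SDC1 (−0.16) and GBP2 (−0.22), and in UC active vs UC inactive S100A12 (−0.31) and GATA2 (−0.51). For active minus normal in UC vs in CD they were MMP9 (0.079) and CLDN4 (−0.18), and for ileum vs distal colon COL1A1 (0.081), THY1 (0.28) and ETFB (−0.055).

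Under a fixed slide block, MKI67 (−0.24), IL17A (0.15) and IL23R (−0.35) turned in CD active vs CD normal, and FPR2 (−0.16), CCR6 (−0.33) and CD8A (−0.17) in UC active vs UC inactive. The result for CXCR1, UC active vs UC inactive, became −0.012 under that block. As plain differences within slide 5, MKI67 was −0.23, IL17A 0.089 and IL23R −0.37, and within slide 2 CCR6 was −0.39 and CD8A −0.15. With the mean over probes the result for OAS3, UC inactive vs UC normal, was −0.068. Of the other 204 gene results in the text, the mean over probes left 191 with the same direction and call and 13 with the same direction only.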

Other observations

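In the fit with the slide as a random block, 17 genes were called between active and normal mucosa in CD, and they are named here after their values were seen. The transcription factor FOXQ1 rose by log2 3.36 (SE 0.68), the cystine carrier SLC7A11 by 1.77 (SE 0.35), the phosphatase PTPN13 by 1.90 (SE 0.37), the focal adhesion gene TNS4 by 1.88 (SE 0.38), and CYP4X1, ERICH6B and TRIM43 by 1.73, 1.55 and 1.12. Those that fell were SOWAHA (−2.80, SE 0.57), the vasoactive intestinal peptide receptor gene VIPR1 (−2.37, SE 0.51), CAMK2N1 (−1.86, SE 0.34), EPHX2 (−1.70, SE 0.33) and C11orf52 (−1.52). The IgG carrier FCGRT (−1.51, SE 0.31), GPRC5C (−1.17), the membrane protease PRSS8 (−1.15, SE 0.23), the growth factor receptor gene ERBB2 (−1.07, SE 0.22) and NR2F6 (−0.89) fell too. Their adjusted p lay between 0.0113 and 0.0462. In UC active against UC normal mucosa, TRIM43 fell by 1.55 (adjusted p = 2.76e-05), and the other 16 were not called.

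The first principal component held 19.8% of the variance of all genes, and the group accounted for 56.0% and the slide for 65.3% of it. The second held 13.6%, of which the group accounted for 43.9% and the slide for 60.7%. Residuals of the 15 pairs of biopsies from 1 donor correlated across genes with r from −0.30 to 0.42 (median −0.01), against a median of −0.02 for the 805 other pairs.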
